A study of Homo sapiens with 2 samples.

How the data were processed

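Gene expression was measured in RMG-I, an established human ovarian clear cell carcinoma line, and in RMG-I-H, the line that the labels describe as RMG-I stably transfected with the human gene FUT1. Total RNA of each was labelled with Cy3, a green dye, and hybridised to 1 array per group, 2 arrays in all. The labels name no second culture, extract or array of either group. RMG-I is labelled as not transfected, and the labels name no line transfected without FUT1. Both arrays were on one slide and in one scan, per the file headers, so neither slide nor scan date separates the groups. The array labelled RMG-I-H was at position 1 of the slide and RMG-I at position 4, so that place cannot be told apart from the group.

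The arrays were Agilent whole human genome arrays of design 14850, read in 1 colour. The deposited scanner files hold spot intensity on a linear scale in arbitrary units, per the file headers. The spots were read with Agilent Feature Extraction 10.5.1.1, per the submitters' processing notes. The processed intensity used here had been background-subtracted and corrected for spatial trends within the array by that software, and it had not been scaled between arrays, per the file headers. The same files give the scanner software's error of each processed intensity, and its calls of spots well above background, saturated or non-uniform. The deposited value table of the series holds the same processed intensity, rounded to 3 significant digits: no value differed from the scanner file's by more than 0.0072 on the log2 scale. Its medians were 96.7 for the array labelled RMG-I-H and 83.8 for RMG-I, it is linear and not centred, and each column is 1 array and no ratio. The probe annotation's genome build named in the headers differs from that of the gene table used for names, so no genome coordinates are given.

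Each array held 43376 gene spots of 41000 probes. Control spots were left out, as were 165 spots called non-uniform or outlying on either array. The log2 of the processed intensity was shifted so that the 75th percentile of the gene spots was the same on both arrays, and it is given below as scaled signal, in arbitrary units. Repeat spots of a probe were averaged. A gene's value was that of its brightest probe among those well above background on at least 1 array. Where a gene was well above background on 1 array only, the dim side was raised to the lowest scaled signal well above background on that array (13.1 on the array labelled RMG-I-H, 15.3 on RMG-I) if it was below it. Such a ratio is called a bound and is given as "at least" a fold. It is no strict lower limit, since a signal not called well above background can exceed the lowest one that was. For MMP10, for example, the dim side was 15.7 on RMG-I and was used as measured. No gene spot was saturated. The gene-level step was tested on simulated arrays of 14749 genes with a noise SD of 0.20: 98.0% of the genes set 1.5 log2 units apart and 100% of those set 3 apart, 50 each way, passed 2-fold, and 0 other genes did. The altered genes were drawn from those well above background with a scaled signal over 100 on RMG-I. Dim genes and bounds were thus not tested. Noise of that size hardly reaches 2-fold, so the 0 is no rate of false calls in these data.

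Probes were named through their RefSeq accessions with a table of current symbols (GRCh38.p14), used for names and for which genes neighbour each other. Of 26278 probes with such an accession, 25398 matched, which is 96.7%, and 15602 probes in all stayed without a symbol. The named probes covered 17240 genes, of which 15027 were analysed, 14155 measured on both arrays and 872 on one. The other 2213 were well above background on neither array. Genes of the Y chromosome and XIST entered the counts but are not shown singly.

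With 1 array per group there is no replicate error, and no test, p-value or SD between cultures can be given. The error given with a log2 ratio is the scanner software's own, with a median of 0.20 over the genes, and covers neither culture nor labelling. Among 231 probes with 10 spots, the SD of the log2 ratio between spots of a probe had a median of 0.094. Among 3563 genes with exactly 2 measured probes, the probes' log2 ratios differed by a median of 0.27, and by up to 0.95 in 90% of them. The number of arrays limits the precision of every value.

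The ratio is the array labelled RMG-I-H over RMG-I throughout. The size rules (at least 2-fold and 4-fold), 37 gene lists and the rule for naming genes were fixed before the data were examined. The rule named FUT1 and any member of its list at least 2-fold different, the 12 genes each way with the largest ratios measured on both arrays and with all probes on one side of 0, and the 5 each way with the largest bounds. It also named up to 4 members of each list that lay outside the central 95% of random lists or had at least 3 members 2-fold different, and the largest member, if at least 2-fold different, of other lists. The ribosomal and housekeeping lists are given as medians only. Some genes that the rule or a count covers are not reported here singly. Other genes that are named were chosen after their values were seen, and this is said beside them. Each list's median was placed among 10000 random lists of the same size, matched on mean signal in 20 bins. That percentile describes these arrays and is no test of the conditions. On simulated arrays, 4 of 100 unshifted lists fell outside the central 95%, and 40 of 40 lists of 30 genes shifted by 0.30 did. The unshifted lists were themselves random genes, so the 4 of 100 follows from how the range is made. It gives no rate for lists whose genes vary together. The simulated ratios spread by a noise SD of 0.20, against an SD of 0.75 over the real genes. Random ranges are therefore wider here, and the 40 of 40 overstates what the list step can find in these data.

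The alternatives were scaling to the median, quantile normalization, cyclic loess normalization, normexp background correction with offset 50, 2 other filters on dim probes, the mean of a gene's probes, the deposited value table, a signal floor of 50 for the counts, and removal of a slide position trend. The slide position trend is one with spot position within the array, and not with the place of the array on the slide. Each list was placed anew among random lists drawn under each alternative other than the floor. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.

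The spike-in spots were dim and were not used to check the scaling. Their 320 spots had a median processed intensity of 4.13 on the array labelled RMG-I-H and 5.18 on RMG-I, beside 3.14 and 3.28 for the negative controls. Of these spots, 69 and 56 were well above background, and the brightest spike-in probe had a median of 20.4 and 18.5.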

Results

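One array of RMG-I-H and one of its parent line RMG-I were compared, to ask how gene expression differed after FUT1 was introduced. RMG-I is an ovarian clear cell carcinoma line, and FUT1 encodes an alpha-1,2-fucosyltransferase that makes the H precursor of the Lewis y antigen. According to the study's design, RMG-I-H carries more of that antigen than RMG-I. Of the 43376 gene spots, 76.5% were well above background on the array labelled RMG-I-H and 73.9% on that of RMG-I. The 75th percentiles of processed intensity were 808 and 737. There were no replicates, so every value below describes these 2 arrays, and errors are the scanner software's own.

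FUT1, the introduced gene, was not higher on the array labelled FUT1-transfected. Its scaled signal was 3518 there and 4058 on the parental array, a log2 ratio of -0.21 ± 0.20 (scanner error). The array carries 1 FUT1 probe (A_23_P107963), and whether it reads the introduced copy is not known; if it does not, it checks nothing about the label. The measurement does not show the rise that the label calls for, and it does not decide whether the label holds. Each direction below is therefore that of the array labelled RMG-I-H over the array labelled RMG-I. With normexp background correction the FUT1 log2 ratio was -0.35.

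None of the 19 analysed members of the fucosylation list differed by 2-fold or more, and their median log2 ratio was -0.13, at percentile 14.8 of matched random lists. Among these, chosen after their values were seen, FUCA1, a lysosomal fucosidase, had a scaled signal of 22679 against 40107. FUT4, an alpha-1,3-fucosyltransferase, had 1199 against 1967. FUT7 and GFUS, an enzyme of GDP-fucose synthesis, were on the other side of 0, at log2 ratios of 0.91 and 0.72.

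**Figure D1:**
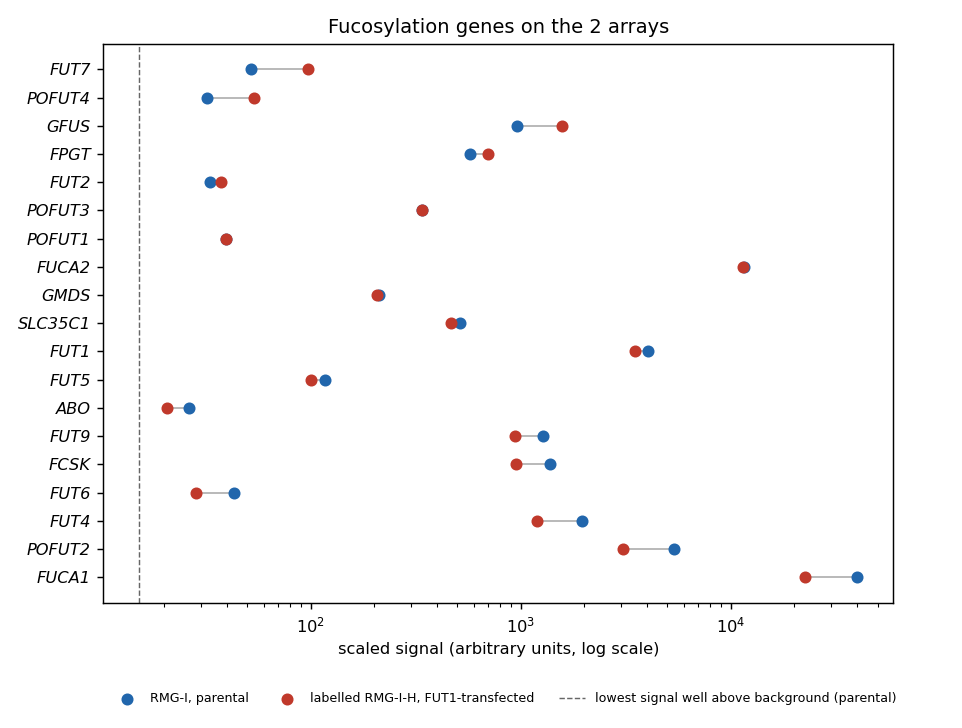
Scaled signal (arbitrary units, log axis) of the 19 analysed genes of fucose transfer, GDP-fucose supply and fucose removal, 1 point per array (blue RMG-I, red the array labelled RMG-I-H), ordered by log2 ratio, with the lowest signal well above background on the parental array dashed. FUT1 lies at 3518 on the array labelled RMG-I-H and at 4058 on RMG-I, and no gene differs by 2-fold.

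Among the other glycosylation genes, single enzymes stood apart while the list medians lay inside the random range in the main setting. B3GNT3, which extends core 1 O-glycans, was 3.68-fold higher and B3GALT6 was 2.20-fold higher on the array labelled RMG-I-H. B3GALT4, a ganglioside galactosyltransferase, was 4.62-fold lower there, and A4GALT, the Gb3 synthase, was 2.17-fold lower. These belong to the list of Lewis and ABH precursor synthesis, where 2 of 18 members were at least 2-fold higher and 3 lower, also B3GNT5 (median -0.22, percentile 7.38). The list is wider than its name, as it holds these enzymes of gangliosides and Gb3. That list lay below the random range under normexp (percentile 1.78) and with the mean of probes (percentile 2.41). Under normexp B3GALT4 had a log2 ratio of -1.59 and A4GALT of -0.85, and with the slide trend removed B3GALT6 had 0.94. Here and below, list members introduced with the word also lay outside the rule for naming and were added after their values were seen. ST6GAL1, which adds alpha-2,6-linked sialic acid, was 5.59-fold higher, and 1 of the 14 sialyltransferases was 2-fold lower, also ST3GAL4 (median -0.30, percentile 4.25). In the list of N- and O-glycan initiation and branching, 4 of 20 members were 2-fold lower and 0 higher: GALNT14, GALNT11, MAN2A1 and GALNT3, between 2.10 and 2.23-fold (median -0.16, percentile 17.2). Of these, MAN2A1 (log2 ratio -0.99) and GALNT3 (-0.96) were under 2-fold with normexp, and GALNT11 (-0.98) with quantile normalization. Under normexp the list lay below the random range (median -0.33, percentile 1.48), and ST6GAL1 had a log2 ratio of 1.58. Of 15 mucins and Lewis antigen carriers, CEACAM1 alone passed 2-fold, at 2.41-fold higher, and its 3 probes were on both sides of 0 (median -0.05, percentile 43.4). Its log2 ratio was 0.65 under normexp and 0.25 with the mean of probes.

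Across all 15027 genes, 1066 were at least 2-fold higher on the array labelled RMG-I-H and 986 were at least 2-fold lower, together 13.7% of the genes. At 4-fold the counts were 151 and 142. Of the 2-fold counts, 150 and 68 were bounds. The log2 signals of the arrays correlated at r = 0.968 across 14155 genes, which are not independent replicates. Under normexp the 2-fold counts were 546 higher and 660 lower, and the 4-fold counts were 60 and 64. That setting adds an offset of 50 to the signals of both arrays, which by itself brings the ratios of dim genes nearer to 1. The lower counts and smaller folds under normexp are therefore partly built into the setting, and the share due to the offset was not measured. Of the 140 genes named by the rule apart from FUT1, 45 had folds over 1.5 times nearer to 1 under normexp, and 25 that passed 2-fold in the main setting no longer did. These genes are noted where their folds are given.

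**Figure D2:**
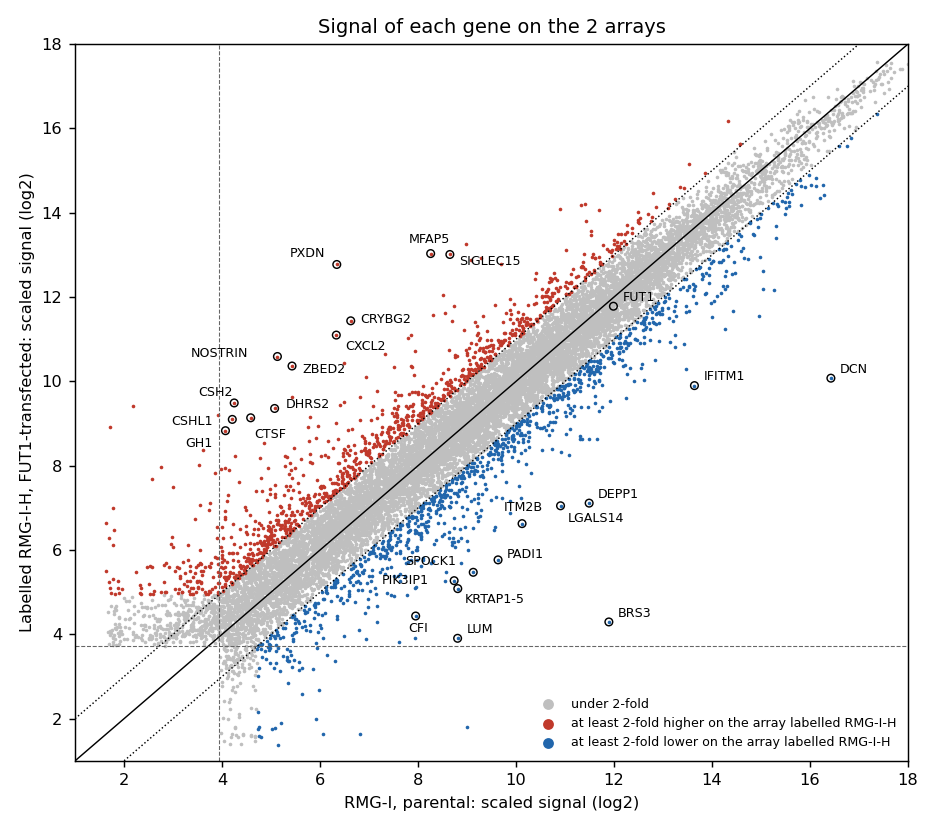
Scaled signal (log2, arbitrary units) of each gene shown on the parental array (x) and on the array labelled RMG-I-H (y), 1 point per gene, with equality as a solid line, 2-fold as dotted lines and each array's lowest signal well above background dashed; signals below a dashed line are drawn as measured, while their colour follows the bound. Genes at least 2-fold higher (red) or lower (blue) lie on both sides of the line in similar numbers, 1066 and 986 over all genes, and FUT1 lies beside the line of equality.

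Among named genes measured on both arrays, the largest ratios higher on the array labelled RMG-I-H were those of PXDN, a peroxidase that crosslinks collagen IV, and NOSTRIN, an adaptor that binds endothelial nitric oxide synthase. PXDN was 86.2-fold higher (6987 against 81.0, log2 ratio 6.43 ± 0.21) and NOSTRIN had a log2 ratio of 5.46 ± 0.24 (1539 against 35.0). ZBED2 was 30.6-fold higher. CRYBG2 was 28.0-fold higher by its brightest probe, but the log2 ratios of its 3 probes ranged from 1.66 to 4.81. MFAP5, a microfibril protein, was 27.3-fold higher and the chemokine CXCL2 27.2-fold, where its 2 probes had log2 ratios of 2.96 and 4.77. CTSF, a lysosomal cysteine protease, was 23.4-fold higher, SIGLEC15 20.5-fold and DHRS2 19.5-fold. CSH2, CSHL1 and GH1, of the growth hormone and placental lactogen cluster, were 37.8-fold, 29.6-fold and 27.1-fold higher. Their sequences are near-identical, so which member gave the signal is uncertain, and the 2 probes of CSHL1 had log2 ratios of 2.03 and 4.89. Under normexp the log2 ratios were 3.16 for CSH2, 2.79 for CSHL1 and 2.61 for GH1, and 5.37 for PXDN, 3.83 for NOSTRIN, 3.55 for ZBED2, 3.72 for CXCL2, 2.87 for CTSF and 2.57 for DHRS2. Among genes well above background on that array only, EFHB was at least 38.4-fold higher by its brightest probe (log2 bounds of 1.99 and 5.26 for its 2 probes), SCEL at least 31.8-fold, TMEM252 at least 21.8-fold and SAGE1 at least 16.9-fold. SERF1A was at least 44.6-fold higher, with doubt over the source of the signal, since it has a near-identical copy. Under normexp the log2 ratios of these 5 genes ranged from 1.98 for SAGE1 to 3.06 for SERF1A.

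Among named genes measured on both arrays, the largest ratios on the other side were those of BRS3, a bombesin receptor family member, and DCN, the matrix proteoglycan decorin. BRS3 was 194-fold lower on the array labelled RMG-I-H (19.6 against 3806, log2 ratio -7.60 ± 0.31). DCN was 81.6-fold lower (1078 against 87994, log2 ratio -6.35 ± 0.20), and LUM, the related proteoglycan lumican, was 29.9-fold lower. DEPP1 was 20.8-fold lower, PADI1 14.6-fold and LGALS14 14.5-fold. IFITM1, which restricts virus entry, was 13.4-fold lower, and its family is near-identical in parts. KRTAP1-5 was 13.2-fold lower, SPOCK1 12.6-fold, CFI (complement factor I) 11.4-fold, ITM2B 11.3-fold and PIK3IP1, an inhibitor of PI3K, 11.0-fold. Among genes well above background on the parental array only, SRGN was at least 38.9-fold lower, SLC35F3 at least 13.7-fold, CHI3L1 at least 8.54-fold and BARX2 at least 6.05-fold. STRC was at least 16.2-fold lower, but it has a near-identical pseudogene. Under normexp the log2 ratios were -5.41 for BRS3, -2.72 for LUM, -2.92 for PADI1, -3.22 for LGALS14, -2.45 for KRTAP1-5, -2.44 for SPOCK1, -1.80 for CFI and -2.13 for PIK3IP1, and those of the 5 bounds ranged from -1.10 for BARX2 to -3.37 for SRGN.

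Of the 37 gene lists, 6 had medians above the central 95% of random lists, 7 below and 24 inside. If each list behaved like randomly drawn genes, 1.85 would be expected outside. Genes of a list can vary together, which places lists outside more often, so the excess over 1.85 is no measure of the conditions. Some lists share members. Of the 13 outside, 7 stayed outside under each of 9 alternative settings, against random lists drawn under that setting, and 6 came inside under at least 1. Scaling to the median shifts every log2 ratio alike, and the deposited value table is the same signal rounded. Those settings could hardly change a list's place, so they add little to the count of 9.

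**Figure D3:**
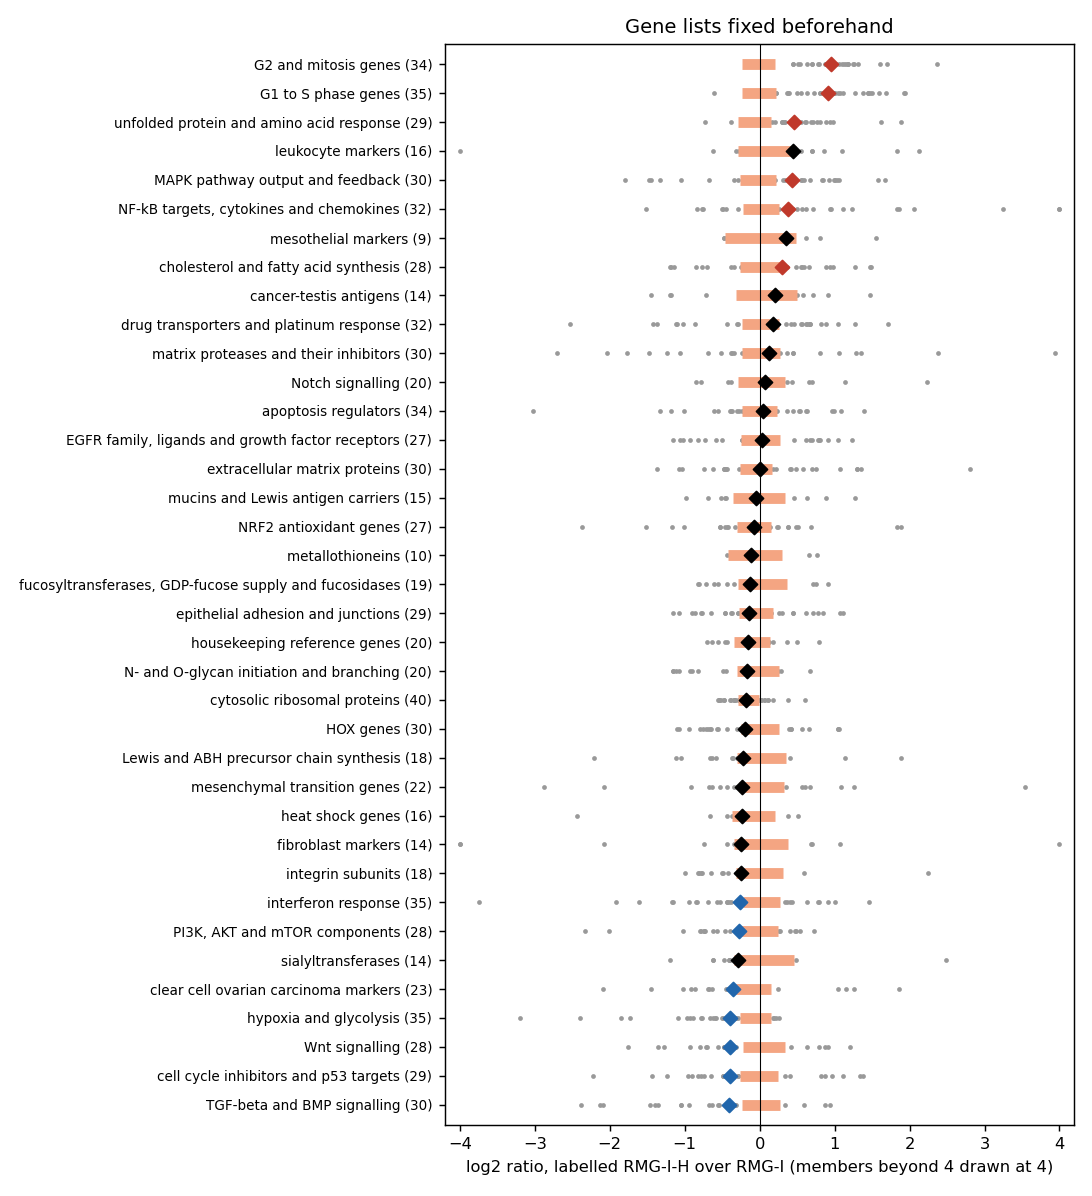
Log2 ratio (array labelled RMG-I-H over RMG-I) of the analysed members of each of the 37 gene lists, 1 grey point per gene (beyond 4 drawn at 4), with the list median as a diamond and the central 95% of 10000 random list medians as an orange bar; the number of analysed genes is in parentheses. The 6 medians above the bar are red and the 7 below it blue; both cell cycle lists lie highest, at 0.91 and 0.95.

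Cell cycle genes were higher on the array labelled RMG-I-H. In the G1 to S phase list, 33 of 35 genes had ratios above 0, 14 were at least 2-fold higher and 0 lower (median 0.91, percentile 100). MCM7, a subunit of the replicative helicase, was 3.82-fold higher, GINS2 3.80-fold, CDC45 3.23-fold and the repressor E2F7 3.02-fold. In the G2 and mitosis list, 33 of 34 genes were above 0, 13 were at least 2-fold higher and 0 lower (median 0.95, percentile 100). HMMR was 5.15-fold higher, the kinetochore genes NDC80 and NUF2 3.24-fold and 3.04-fold, and FOXM1, a transcription factor of mitotic genes, 2.49-fold. The list of cell cycle inhibitors and p53 targets lay below the random range (median -0.40, percentile 0.090), with 3 of 29 members 2-fold higher and 3 lower. GADD45B was 4.69-fold and SESN1 2.72-fold lower, whereas TP53I3 and PLK3 were 2.59-fold and 2.53-fold higher. The counts hold also CDKN1C on the lower side and FAS on the higher.

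Inflammatory genes were among those with large ratios. In the list of NF-kB targets and cytokines, 8 of 32 members were at least 2-fold higher and 1, SOD2, lower (median 0.38, percentile 99.8). CXCL2 stood first, LCN2 (lipocalin 2) was 19.4-fold higher, PTGS2 (cyclooxygenase 2) 9.50-fold, and CSF3 at least 4.18-fold. The list includes 7 bounds, and it came inside the random range under normexp (median 0.11, percentile 96.8) and without a filter on dim probes (0.20, percentile 96.3). CSF3 had a log2 ratio of 0.42 under normexp. Leukocyte markers had a median of 0.44 (percentile 96.2), with ITGAX 4.38-fold, CSF1R 3.58-fold and CD3E 2.15-fold higher but SRGN lower. That median was 0.20 under normexp and 0.17 without the filter, and 0.47 with the mean of probes, then above the random range (percentile 98.0). ITGAX had a log2 ratio of 0.71 under normexp, and CD3E 0.68 under normexp, 0.87 with the mean of probes and 0.96 with the slide trend removed. In the interferon response list, 2 of 35 members were 2-fold higher and 5 lower (median -0.26, percentile 1.29). IFITM2 and IFITM3 were 3.76-fold and 3.06-fold lower beside IFITM1, whereas OAS3, which senses double-stranded RNA, was 2.74-fold higher. The other probe of OAS3 had a log2 ratio of 0.74. The counts hold also MX1 and IFI44 on the lower side and IFIT2 on the higher. The interferon list came inside the random range under normexp (percentile 5.95).

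The lists of growth factor signalling differed in direction. In the MAPK output list, 21 of 30 members were above 0 (median 0.43, percentile 99.99), with 5 at least 2-fold higher and 5 lower. SPRY2 and PHLDA1 were 3.19-fold and 2.98-fold higher, while JUNB and the phosphatase gene DUSP1 were 3.47-fold and 2.79-fold lower. The other probe of JUNB had a log2 ratio of -0.93. The counts hold also SPRY4, EPHA2 and CCND1 on the higher side, and DUSP10, IER3 and JUN on the lower. In the TGF-beta and BMP list, 8 of 30 members were 2-fold lower and 0 higher (median -0.41, percentile 0.060). ID3 was 5.22-fold lower, TGFB2 at least 4.39-fold, TGFBI 4.25-fold and ID1 2.77-fold. Under normexp ID3 had a log2 ratio of -1.36 and TGFB2 of -0.76. In the list of PI3K, AKT and mTOR components, 3 of 28 were 2-fold lower and 0 higher (median -0.27, percentile 2.25). These were the insulin receptor substrate IRS1, 5.03-fold, DDIT4, an inhibitor of mTORC1, 4.04-fold, and MTOR, 2.03-fold. The Wnt list had 1 of 28 members 2-fold higher and 3 lower (median -0.39, percentile 0.040). FZD3 was 3.38-fold lower, TCF7L2 at least 2.55-fold and WNT5A 2.41-fold, and DKK3, which counters Wnt signals, was 2.30-fold higher, with its other probe at a log2 ratio of 0.06. Under normexp TCF7L2 had a log2 ratio of -0.39 and DKK3 of 0.97, and DKK3 had 0.63 with the mean of probes. With the mean of a gene's probes both lists came inside the random range, PI3K at a median of -0.10 (percentile 22.9) and Wnt at -0.15 (percentile 6.24). The PI3K list came inside as well without a filter on dim probes (percentile 11.3) and with the slide trend removed (percentile 3.91), where MTOR had a log2 ratio of -0.79.

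The EGFR family and growth factor list lay inside the random range (median 0.03, percentile 55.5), with 2 of 27 members 2-fold higher and 3 lower. EGFR was 2.09-fold lower, and MET, the hepatocyte growth factor receptor, 2.06-fold higher. EREG was at least 2.35-fold higher, and IGF1R was 2.24-fold lower by its brighter probe, with its other probe on the other side of 0. The lower genes include also PDGFA. EREG had a log2 ratio of 0.36 under normexp, IGF1R -0.46 with the mean of probes and MET 0.99 with scaling to the median. The Notch list was inside as well (median 0.07, percentile 62.6), with the ligand gene JAG1 4.72-fold higher and also HEYL higher, as 2 of 20 members past 2-fold.

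Genes of hypoxia and glycolysis were lower on the array labelled RMG-I-H, with 27 of 35 below 0, 5 at least 2-fold lower and 0 higher (median -0.39, percentile 0.080). ANGPTL4 was 9.15-fold lower, CA12 (carbonic anhydrase 12) 5.29-fold, ADM (adrenomedullin) 3.61-fold and P4HA1 3.31-fold, with also SLC16A3 past 2-fold. In the list of the unfolded protein and amino acid response, 24 of 29 members were above 0 (median 0.46, percentile 100), of which 2 passed 2-fold and 0 were 2-fold lower. SLC7A11, the cystine transporter, was 3.69-fold higher and ASNS, asparagine synthetase, 3.07-fold. CHAC1 and DNAJC3 were 1.97-fold and 1.92-fold higher. Cholesterol and fatty acid genes had a median of 0.30 (percentile 98.5), with 3 of 28 members 2-fold higher and 3 lower. SREBF1, a transcription factor of lipid synthesis, was 2.81-fold higher, FADS2 2.78-fold and CYP51A1 2.42-fold, and MVK was 2.30-fold lower, and also ELOVL6 passed 2-fold on that side. That list came inside the random range under normexp (percentile 95.9).

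In the list of clear cell ovarian carcinoma markers, 4 of 23 members were at least 2-fold higher and 3 lower (median -0.35, percentile 1.39). The cytokine IL6 was 3.64-fold higher and DPP4 2.40-fold higher, whereas ARID1B was 4.28-fold and NAPSA 2.72-fold lower, the latter with its other probe at a log2 ratio of -0.32 and the mean of its probes at -0.88. The counts hold also MET and F3 on the higher side and ZNF217 on the lower. The list came inside the random range under 5 of 9 alternatives, among them the mean of probes (median -0.17, percentile 25.5) and quantile normalization, where its median of -0.22 was on the edge of the range.

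Adhesion and matrix genes showed large single differences with medians inside the random range in the main setting. Of 18 integrin subunits, ITGA2 alone passed 2-fold, at 4.74-fold higher (list median -0.25, percentile 6.17). The list lay below the random range under quantile normalization (percentile 1.93) and cyclic loess (percentile 2.32), and its median was -0.06 with the mean of probes. Among 30 extracellular matrix genes, 5 were at least 2-fold higher and 3 lower. TNC (tenascin C) was 6.97-fold higher and THBS1 (thrombospondin 1) 2.59-fold lower. COL5A2 was 2.47-fold higher by its brightest probe and had another probe on the other side of 0. Under normexp COL5A2 had a log2 ratio of 0.82 and THBS1 was just under 2-fold, and the mean of the probes of COL5A2 was 0.56. The counts hold also LAMA3 and COL3A1, the latter as a bound, on the higher side, and COL18A1 and COL4A5 on the lower. The matrix list had a median of 0.00 (percentile 68.8), which was 0.12 under cyclic loess, 0.17 with the mean of probes and -0.06 with scaling to the median. Of 30 matrix proteases and inhibitors, 5 were 2-fold higher and 6 lower (median 0.13, percentile 79.7). MMP10 was at least 15.4-fold higher and PLAU (urokinase) 5.18-fold higher, while ADAMTS1 and SERPINB5 were 6.51-fold and 4.10-fold lower, the latter with its other probe at a log2 ratio of -0.97. The higher genes include also MMP1, TIMP4 and ADAMTS5. MMP10 had a log2 ratio of 2.04 under normexp. In the epithelial junction list, 2 of 29 were higher and 2 lower (median -0.14, percentile 21.1). CLDN1 and GRHL2 were 2.10-fold and 2.17-fold higher, and CLDN4 and CTNNB1 (beta-catenin) 2.22-fold and 2.10-fold lower. Under normexp CLDN1 (log2 ratio 0.94), GRHL2 (0.79) and CTNNB1 (-0.99) were under 2-fold, and so was CTNNB1 with the mean of probes.

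The mesenchymal transition list had 3 of 22 members 2-fold higher and 2 lower (median -0.23, percentile 5.04). NT5E (CD73) was 11.6-fold and FOXC2 2.39-fold higher, while CDH2 (N-cadherin) and VIM (vimentin) were 7.37-fold and 4.23-fold lower. The higher genes include also ENG. The list lay below the random range under normexp (percentile 2.15). Fibroblast markers, of which VIM is one, had 2 of 14 members 2-fold higher and 3 lower (median -0.24, percentile 8.25). DCN, LUM and VIM were lower and MFAP5 and, as a bound, also COL3A1 higher. That median was 0.06 without a filter on dim probes. Mesothelial markers had a median of 0.35 (percentile 92.2), and LRRN4 was at least 2.93-fold higher as the only one of 9 past 2-fold, with a log2 ratio of 0.27 under normexp. The median was -0.27 over genes well above background on both arrays, -0.13 without a filter and 0.09 under normexp.

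Among genes of drug response and cell death, members went both ways. Of 32 drug transporter and platinum response genes, 3 were at least 2-fold higher and 6 lower (median 0.18, percentile 91.8). SLC31A2, a copper transporter family member, was 3.27-fold higher, while GSTM3, GSTA4 and ABCC5 were 5.77-fold, 2.67-fold and 2.57-fold lower. The higher genes include also TYMS and ATP7B. Of 34 apoptosis regulators, 2 were higher and 4 lower (median 0.05, percentile 67.5). The proapoptotic genes BMF and BCL2L11 were 8.16-fold and 2.52-fold lower and the antiapoptotic BCL2 2.27-fold lower. The antiapoptotic BCL2L1 was 2.63-fold higher, with its other probe at a log2 ratio of 0.88. The counts hold also MCL1 on the lower side and BIK on the higher. BMF had a log2 ratio of -1.37 under normexp, and BCL2L11 was just under 2-fold there and with the mean of probes (-0.98). The apoptosis median was 0.18 with the mean of probes, and -0.01 with scaling to the median. Of 27 NRF2 antioxidant genes, 2 were higher, SLC7A11 and NQO1 (3.56-fold), and 4 lower, AKR1C1 (5.16-fold), SOD2 (2.86-fold) and also AKR1C3 and FTL. NQO1 had a log2 ratio of 0.99 under normexp. Their median was -0.08 (percentile 50.98), and it was 0.01 under quantile and under cyclic loess normalization. GSTM3 and AKR1C1 belong to families of near-identical genes.

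In the remaining lists, 0 of 10 metallothioneins passed 2-fold (median -0.11, percentile 38.5). HSPB8 was 5.43-fold lower, the only one of 16 heat shock genes past 2-fold (median -0.24, percentile 14.1). Of 14 cancer-testis antigens, MAGEC2 was 2.77-fold higher, while PRAME was 2.74-fold, MAGEA8 2.30-fold and PAGE2 at least 2.28-fold lower (median 0.20, percentile 70.0). Under normexp MAGEC2 had a log2 ratio of 0.67, MAGEA8 of -0.53 and PAGE2 of -0.37. Of 30 HOX genes, 3 were 2-fold higher and 2 lower (median -0.19, percentile 5.88). HOXA5 and HOXB13 were 2.15-fold and 2.10-fold lower, HOXA13 was 2.09-fold higher, HOXC8 at least 2.06-fold higher and also HOXC5 higher. The HOX list lay below the random range under normexp (percentile 0.92), where HOXA5 had a log2 ratio of -0.93, HOXA13 of 0.29 and HOXC8 of 0.33. HOXA13 was under 2-fold as well with quantile, cyclic loess and slide trend removal, and HOXC8 with quantile normalization and scaling to the median. Of 40 cytosolic ribosomal protein genes and 20 housekeeping genes, 0 passed 2-fold. Their medians were -0.18 and -0.16, inside the random range at percentiles 33.0 and 31.2. Those medians were 0.01 and 0.00 under quantile normalization and 0.02 and 0.01 under cyclic loess, so neither direction held under every scaling.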

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

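The tests of scaling, exchanged labels, probe place and growth state below were chosen after their results were seen. Those of slide position and shifted runs were chosen after the patterns they address were seen, and set before their own outcomes.

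Probes without a matched gene symbol carried signal that the report does not use. Of 10427 such probes analysed, 81 were at least 4-fold brighter on the array labelled RMG-I-H and 74 were at least 4-fold dimmer. The largest differences were those of A_24_P725998 (21690 against 160, 136-fold brighter) and A_23_P80583 (9244 against 427, 21.6-fold brighter). On the other side were A_24_P760945 (49.9 against 918, 18.4-fold dimmer) and A_24_P882959 (613 against 9112, 14.9-fold dimmer).

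FUT1 was not higher on the array labelled FUT1-transfected, where the label calls for more. Scaling does not account for it: the highest FUT1 log2 ratio over the main setting and its alternatives was -0.11. An exchange of the labels cannot be told apart from the labels as given, since the gene was 0.21 log2 units higher on the array labelled parental and the probe may not read the introduced copy. A probe outside the introduced part of the gene stays open as well, as there is 1 probe for FUT1 and no other to set it against. Loss or silencing of the introduced gene was not tested.

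The cell cycle lists were higher on the array labelled RMG-I-H. Scaling or a trend with signal is argued against, since the lower of their medians over the other scalings, background correction, filters and probe choices was 0.81, above the random range. A trend with spot position within the array is as well, with 0.89 after it was removed. So are the shifted runs of neighbouring genes, since 33 of 35 G1 to S genes and 34 of 34 G2 and mitosis genes lie outside them. The lower median over members outside was 0.91, which leaving out so few genes could hardly have moved. The place of each array on the slide cannot be told apart from the group. The growth state of the cultures, such as their density at harvest, cannot be told apart from the transfection with 1 culture per group. The transfection stays open as a biological explanation, untested. With no line transfected without FUT1, FUT1 itself cannot be told apart from other effects of making a stably transfected line.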

How the results depend on the processing

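The background correction by normexp on the median spot intensity and the removal of the slide position trend were chosen after seeing the data; the planned normexp on the mean spot intensity was not run, for want of that column in the files used here. The placing of each list among random lists drawn under each alternative was chosen after seeing the data as well. Of the 13 lists outside the random range, 7 stayed outside under all 9 alternatives: TGF-beta, MAPK, both cell cycle lists, cell cycle inhibitors, hypoxia, and the unfolded protein response. The other 6 came inside under some: clear cell under 5, PI3K under 3, NF-kB under 2, and Wnt, cholesterol and interferon under 1 each. Of the 24 inside, 6 lay outside under some. None of the 13 passed to the other side of the range, and 24 of 333 medians moved by more than the SD of their random lists. For the named genes other than FUT1, 982 of 1242 values stayed within the spot SD of 0.094, 260 moved and 0 reversed. Scaling to the median, a constant shift smaller than that SD, and the rounded value table could hardly move a value or a median past these limits. Under quantile normalization the clear cell median was -0.22, the ribosomal 0.0078 and the housekeeping 0.0016; under cyclic loess the matrix median was 0.12, the ribosomal 0.025 and the housekeeping 0.0068. Under normexp there were 546 genes 2-fold higher, 60 genes 4-fold higher and 64 genes 4-fold lower, FUT1 was -0.35, and the medians were -0.33 (N- and O-glycans), 0.82 (G2 and mitosis), 0.11 (NF-kB), 0.090 (mesothelial), 0.20 (leukocyte) and -0.028 (housekeeping). With genes well above background on both arrays the mesothelial median was -0.27. Without a filter 257 genes were 4-fold higher, and the medians were 0.20 (NF-kB), 0.063 (fibroblast), -0.13 (mesothelial) and 0.17 (leukocyte). With the mean of probes the medians were -0.055 (integrins), 0.17 (matrix), -0.10 (PI3K), -0.15 (Wnt), 0.18 (apoptosis) and -0.17 (clear cell). With the slide trend removed the MAPK median was 0.29. The offset of 50 in normexp by itself makes the ratios of dim genes smaller in size, so shrinkage under that setting is partly built in. How much of it came from the offset was not measured, and the cause of the other changes was not tested. The share of higher genes among those 2-fold different was 51.9%, and 45.3% to 53.8% under the alternatives. Signal near background limits what the 872 genes measured on 1 array can show.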

Other observations

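The families and gene runs below were chosen after the data were seen, and so were the tests of chance gene order and gene dosage; those of slide position and cross-hybridization were chosen after the runs were seen and set before their own outcomes.

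Of the clustered histone genes, H2B and H2A lay on opposite sides and H3 and H4 inside the random range. All 16 clustered H2B genes analysed had ratios above 0, and 9 were at least 2-fold higher on the array labelled RMG-I-H (median 1.01, between 0.95 and 1.06 over the scalings and normexp). Of 14 clustered H2A genes, 10 were below 0 and 4 at least 2-fold lower (median -0.63, between -0.69 and -0.48). H3 had a median of -0.05 (percentile 29.1) and H4 of -0.26 (percentile 8.13, 1 of 12 genes 2-fold higher and 4 lower). H2BC12 was 2.58-fold higher and H2AC17 2.58-fold lower. Members of each type are near-identical, so single genes are uncertain.

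Clusters of genes with placental members parted as well. All 9 pregnancy-specific glycoprotein genes analysed were at least 2-fold lower on the array labelled RMG-I-H (median -2.38), with PSG1 at 2995 against 31644 and PSG8 at 4571 against 39547. All 5 growth hormone and placental lactogen genes, GH2 as a bound, were at least 2-fold higher (median 4.76, and 2.61 under normexp). Whether the probes within each of these clusters read separate transcripts was not checked, so their members may not be independent readings. The protocadherin beta cluster had 5 of 13 genes at least 2-fold higher and 0 lower, PCDHB5, PCDHB14 and PCDHB16 as bounds, with PCDHB2 7.66-fold higher, but its median of 0.47 lay inside the central 95% of random lists (percentile 95.1). It was 0.29 under normexp, then at percentile 99.8. Among 265 families of symbols with at least 8 genes, 7 lay outside the central 99% of random lists. Families of randomly drawn genes would give 2.65, but genes of a family can vary together. MCM, MRPL and NEK genes lay above it, and PSG, RAB, ZBTB and ZNF genes below it. MCM, PSG and ZNF stayed outside under the other scalings and normexp. The others came inside under at least 1 of these: NEK at percentile 93.8 under normexp, RAB at 2.61 under cyclic loess, ZBTB at 0.69 under normexp and MRPL at 99.4 under quantile normalization. The 389 ZNF genes had a median of -0.23. Of these, 67 lie in the runs of neighbouring genes described next, with a median of -0.62, and the 322 others had a median of -0.15.

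Neighbouring genes were shifted together in 7 runs that held 1225 of 15012 genes, 8.16%. The runs from MSANTD4 to ABCG4, GTF2F2 to SOX1, ERH to PACS2, TMEM248 to MKLN1 and QNG1 to OR1Q1 had medians of 0.40, 0.49, 0.39, 0.48 and 0.37. Those from RPL18 to ZSCAN4, which holds FUT1, and from VTA1 to DLL1 had medians of -0.42 and -0.47. The 100 genes around FUT1 had a median of -0.22. The run from TMEM248 to MKLN1 holds MCM7 and MET, named above. The runs held 12.3% of the genes at least 2-fold different. Chance order is argued against, since 27 windows of 100 genes lay beyond the highest of 1000 shuffled orders, 0.36. A trend with spot position within the array is too, as each run kept at least 85.9% of its median with it removed. Cross-hybridization among zinc finger genes, 58 of the 225 in the run from RPL18, was not settled: the run's other genes had a median of -0.27, neither near 0 nor beyond the shuffled range. As a hypothesis, the cell populations may differ in the copy number of these stretches. That at least 68.0% of each run's genes lay on its side of 0 follows largely from how the runs were picked and decides nothing. RNA alone cannot tell copy number from regional regulation, and no DNA measurement was analysed here.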
